A study of Homo sapiens with 12 samples.

How the data were processed

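The series holds 12 RNA sequencing libraries of K-562 cells, 3 in each of 4 groups. Per the labels' protocols, stable lines were selected with G418, RNA was purified with an RNeasy kit, and libraries of poly(A) RNA were made with a stranded TruSeq kit. Per the series' design text, RNA was taken 24 hours after siRNA transfection and sequenced as 125-bp paired-end reads on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles. The same text calls the 3 replicates separate experiments.

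The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library), with a column per library and 60658 rows. Per the submitters' processing notes, the software was bcl2fastq 2.17.1.14, Trimmomatic 0.33, TopHat2 2.0.13 and Cufflinks 2.2.1, with the GRCh38 assembly. The annotation, the Cufflinks program that wrote the values and its use of strand are not given in the sources used here. A symbol was found for 56950 rows, and 31954 rows are at 0 in every library. No column belongs to other samples. No pair of libraries holds identical values. Whether whole reads could be recovered was checked on genes with low values. A median of 6.6% of the ratios between libraries lay within 2% of the pair's median, so read counts and depth stayed unknown and no count model was used. FPKM values depend on a gene's transcript length and on the few most abundant transcripts of a library. Ribosomal protein genes held 22.0%, 15.9% and 15.0% of the FPKM total in MYB_KnockDown replicates 1, 2 and 3, and 9.6% to 13.3% in the 9 other libraries. Mitochondrial genes held 10.3% to 20.5%.

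Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were kept, 13393 in all, 98.4% of them with a symbol and 97.8% with a transcript length. Values were analysed as log2(FPKM + 1), and every log2 change is on that scale, which understates the change of genes with low FPKM. All 12 libraries entered 1 linear model with limma 3.58.1 in R 4.3.3, with a mean for each group, a variance trend and 8 residual degrees of freedom. The 6 contrasts between groups were tested with Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. Since the fit shares 1 estimate of spread, a library of any group can move the calls of every comparison. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Gene symbols come from a table of Ensembl identifiers, transcript lengths from the canonical transcripts of the GENCODE annotation, and GRCh38 coordinates from a table of NCBI RefSeq genes on that assembly.

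The 26 gene lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists of a comparison. With an estimated correlation none of the 13 list calls held in any comparison. Set tests were recomputed without MYB_KnockDown replicate 1 and with no other library left out. Named genes were MYB; the 6 largest increases and 6 largest decreases of each main comparison among called genes whose groups do not overlap and whose mean FPKM is at least 5; up to 4 called members of each list with at least 3 called members or a passing set test; and 18 genes fixed in advance, of which BCL2 was not tested. Small RNAs, MTRNR2L copies and clone names were left out of the largest changes. Some genes that the rule takes are not reported here. Genes with near-identical copies (HBG1 and HBG2, HSPA1A and HSPA1B, histones, ribosomal proteins) have uncertain separate values.

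A knockdown gene was counted as moved back when it was called in the opposite direction in a rescue against the knockdown. These comparisons share the knockdown libraries, so overlap and correlation were also computed in 40 simulations with 1 pooled spread, of unchanged groups and of rescues left at the knockdown level. The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization, median-ratio scaling, robust moderation, the replicate number as a block, an adjusted p under 0.01, only the 6 libraries compared, an estimated correlation for lists, and leaving out each library. Library weights, removal of genes listed at 0 in a whole group, removal of each library's trend with transcript length, lists and rescue comparisons without MYB_KnockDown replicate 1, counts without each library of the groups not compared, the block together with the length trend removed, called list members without each library, correlations and moved-back counts from different knockdown libraries, and 100 simulations with the spread of each group were added after seeing the data. Whether replicate numbers pair libraries was checked by correlating, over genes, deviations from the group means. Between the 2 rescue lines the 3 pairs with the same number in their titles had r of 0.153 to 0.233 and the other pairs -0.22 to 0.062, so the numbers were taken to pair these libraries. The pairing rests on this check alone, since the labels do not say what a number shares. In each other comparison at least 1 pair had an r of 0.1 or less, and the numbers were not used as pairs.

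The procedure was tested in 10 runs of simulated independent genes with 1 pooled spread, 200 of 13393 changed. For the knockdown, 73.9% of 2-fold and 97.4% of 4-fold changes were recovered, 0 with the wrong sign, and 4.9% of calls were false. Between the rescue lines the shares were 72.1%, 98% and 4.3%. A list shifted by 0.5 on the log2 scale was called in all runs. Correlated genes and the wider knockdown spread were not tested.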

Results

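Gene expression was measured by RNA sequencing in K-562 cells, a human erythroleukemia line that makes embryonic and fetal globins. The design has 4 groups of 3 libraries each. The control group is a stable line carrying the 3xTY1 tag alone, transfected with a non-targeting siRNA. The knockdown group is the same line transfected with an siRNA against MYB. The 2 rescue groups are separate stable lines that received the MYB siRNA while expressing tagged wild-type MYB or tagged D152V, a form of MYB named for an amino acid substitution. RNA was taken 24 hours after transfection, in 3 separate experiments per the series' design text. Values are FPKM per gene, and 13393 genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested. Read counts and library depth are unknown. FPKM totals ran from 672616 to 798362 in 11 libraries and reached 1215578 in MYB_KnockDown replicate 1. Over the tested genes that library correlated with the other knockdown libraries at r of 0.929 and 0.93, while every other pair within a group had an r of at least 0.983. Each leading count is therefore also given without that library, singled out after seeing the data. For gene lists, counts in 11 libraries leave out that library and are given where either count moved by over 1.5 times. A range over settings is that of the adjusted p over all alternatives run for the result.

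The targeted gene was examined first. MYB (ENSG00000118513; GRCh38 chromosome 6, 135181308 to 135219172, protein coding), a transcription factor of hematopoietic progenitors, was measured at 120.1 ± 14.2 FPKM (mean ± SD, n = 3) in control libraries and 30.2 ± 3.58 in knockdown libraries, 25.1% of the control level. On the log2(FPKM + 1) scale it fell by 1.96 (SE 0.13, limma adjusted p = 3.03e-05). The wild-type rescue libraries held 124 ± 8.87 FPKM, 103.4% of control, and the D152V rescue libraries 91.0 ± 8.11 FPKM, 75.8% of control. MYB rose against the knockdown by 2.01 in the wild-type rescue (limma adjusted p = 5.60e-06) and by 1.56 in the D152V rescue (limma adjusted p = 3.22e-05). The table gives 1 value per gene, so introduced and endogenous MYB transcripts are not separated. Between the 2 rescue lines MYB differed by -0.44 (D152V minus wild-type, limma adjusted p = 0.0494). That call was lost in 13 of 14 other settings, in which the adjusted p ran from 0.00542 to 0.164, and every one of the 6 rescue libraries ended the call when left out. With the replicate number as a block it was 0.0640.

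**Figure D1:**
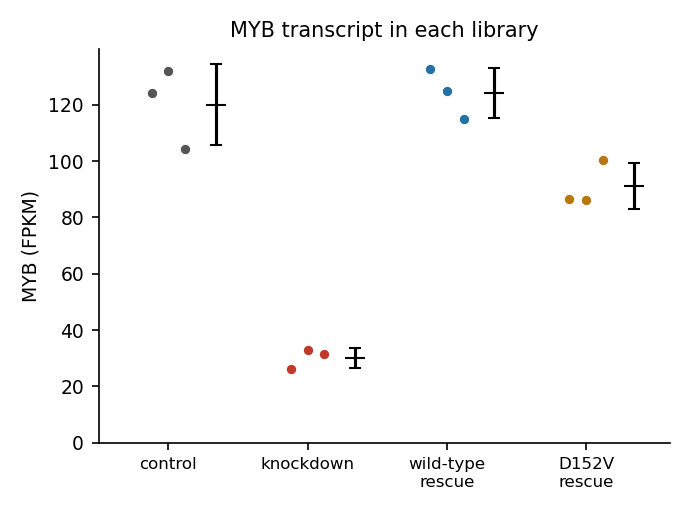
MYB transcript in FPKM (vertical axis) in each of the 12 libraries (points) of the control, knockdown, wild-type rescue and D152V rescue groups, with the group mean and SD in black (n = 3). The knockdown libraries lie between 26.1 and 32.9 FPKM, all below the lowest of the other 9 libraries at 86.2 FPKM.

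Knockdown of MYB was compared with control siRNA in the same stable line, which asks which transcripts change when MYB is depleted. MYADM (GRCh38 chromosome 19, 53865628 to 53876435), a membrane protein of myeloid cells, fell from 65.5 ± 9.17 to 13.3 ± 5.69 FPKM (log2 change -2.29, SE 0.29, limma adjusted p = 0.00254; SD, n = 3 here and below). The long noncoding RNA UCA1 (GRCh38 chromosome 19, 15828947 to 15836321) fell from 109.5 ± 6.41 to 32.7 ± 8.74 FPKM (log2 change -1.74, SE 0.21, adjusted p = 0.00192). MYC (GRCh38 chromosome 8, 127735434 to 127742951), a driver of cell growth and an established MYB target, fell from 204 ± 22.6 to 96.7 ± 23.4 FPKM (log2 change -1.10, adjusted p = 0.00738). LMO2 (GRCh38 chromosome 11, 33858576 to 33892076), a bridging subunit of the TAL1 and GATA complex, fell from 27.9 ± 4.88 to 12.3 ± 2.27 FPKM, and STAT5A (GRCh38 chromosome 17, 42287439 to 42311943), a mediator of cytokine signals, from 141 ± 17.4 to 67.5 ± 13.7 FPKM (log2 changes -1.12 and -1.07, adjusted p = 0.00637 and 0.00703). These 5 genes and MYB passed the test in every setting computed for single genes. The fixed rule also took NKG7 and S100A13, which rose, and NKIRAS2 and the antisense transcripts HNRNPK-AS1 and TAB3-AS2, which fell (log2 changes 2.08, 1.97, -1.78, -1.89 and -1.83). All 5 of these calls were lost without any 1 of siRNA_Control replicates 1, 2 and 3, with adjusted p from 0.0542 to 0.144, and that of TAB3-AS2 also without MYB_KnockDown replicate 1 (0.0611; 0.0244 to 0.144 over settings). With no filter on low values the same 5 calls were lost (adjusted p from 0.0502 for NKIRAS2 to 0.104 for TAB3-AS2). With a pseudocount of 0.1 those of HNRNPK-AS1 and TAB3-AS2 were lost (0.0643 and 0.0558). Over settings the adjusted p ran from 0.00696 to 0.0990 for NKG7, 0.00183 to 0.136 for S100A13, 1.50e-04 to 0.0752 for NKIRAS2 and 0.00446 to 0.0992 for HNRNPK-AS1. Reads of the antisense transcripts may be shared with the opposite strand, since the use of strand in the quantification is not given in the sources used here.

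Several hematopoietic regulators lay lower in the knockdown libraries. Of 25 measured genes in a list of hematopoietic transcription factors, 7 fell and 1 rose (10 and 3 adjusted over the list alone, 9 and 2 in 11 libraries), and as a set the list did not pass (camera adjusted p = 0.0563). LDB1, a cofactor that joins LMO2 complexes, fell from 66.1 ± 0.597 to 34.8 ± 15.4 FPKM, and ZBTB7A, a repressor of fetal globin genes, from 9.12 ± 1.59 to 4.03 ± 0.350 FPKM (adjusted p = 0.0369 and 0.0165). TAL1 rose from 36.7 ± 1.95 to 51.7 ± 9.08 FPKM (adjusted p = 0.0448). KIT, the stem cell factor receptor, fell from 7.15 ± 2.24 to 3.24 ± 1.39 FPKM (log2 change -0.96, adjusted p = 0.0401). GATA2 stood at 66.3 ± 3.04 and 48.3 ± 5.36 FPKM and did not pass (adjusted p = 0.0510, 0.0129 without MYB_KnockDown replicate 1, 0.0416 with a mean FPKM of at least 5 and 0.0358 after quantile normalization; 0.0129 to 0.162 over settings). GATA1, KLF1, RUNX1, SPI1 and CEBPB had adjusted p values of 0.547, 0.488, 0.163, 0.157 and 0.0664. CEBPB passed without MYB_KnockDown replicate 2 (0.0494) or replicate 3 (0.0310; 0.0310 to 0.188 over settings). The list of MYB targets from the literature had 1 higher and 5 lower of 17 (1 and 6 adjusted over the list alone, camera adjusted p = 0.160). EP300, an acetyltransferase that binds MYB, fell from 8.84 ± 0.447 to 4.35 ± 1.44 FPKM, with SIN3A and PIAS1 also lower (log2 changes -0.92, -0.85 and -0.77, adjusted p = 0.0155, 0.0195 and 0.0180). Their list of acetyltransferases and MYB cofactors had 1 higher and 3 lower of 31 (1 and 3 adjusted over the list alone, 3 and 10 in 11 libraries, camera adjusted p = 0.0758). The calls of LDB1, TAL1 and KIT were lost when any 1 of the 3 control libraries was left out, and those of ZBTB7A, EP300, SIN3A and PIAS1 without siRNA_Control replicate 1 or 2. TAL1 was also lost without MYB_KnockDown replicates 2 or 3 (adjusted p = 0.0738 and 0.0782) and after quantile normalization (0.0793). With no filter LDB1, TAL1 and KIT were lost (0.0880, 0.0738 and 0.0966). Without siRNA_Control replicates 1, 2 and 3 the adjusted p was 0.119, 0.115 and 0.0883 for LDB1, 0.151, 0.111 and 0.110 for TAL1 and 0.0694, 0.149 and 0.0963 for KIT. For ZBTB7A, EP300, SIN3A and PIAS1 it lay between 0.0635 and 0.0894 without replicate 1 or 2. Over settings it ran from 8.54e-04 to 0.119 for LDB1, 9.36e-04 to 0.151 for TAL1, 0.0233 to 0.149 for KIT, 0.00630 to 0.0789 for ZBTB7A, 0.00168 to 0.0707 for EP300, 0.00316 to 0.0840 for SIN3A and 0.00789 to 0.0894 for PIAS1.

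Ribosomal protein genes lay above their control level in all 3 knockdown libraries. Of 41 measured genes 13 rose and none fell, and 26 rose adjusted over the list alone. RPS19 (GRCh38 chromosome 19, 41860255 to 41872925) went from 464 ± 20.2 to 1693 ± 1487 FPKM and RPS12 from 605 ± 32.4 to 1612 ± 971 FPKM (adjusted p = 0.0417 and 0.0259). The list lay 0.83 above other genes on the log2 scale (camera adjusted p = 7.83e-12; adjusted p = 0.718 with an estimated correlation). The size rested on MYB_KnockDown replicate 1: against the control mean the difference was 1.69 there and 0.46 and 0.34 in the other knockdown libraries. Without that library the list lay 0.40 above other genes with 24 of 41 genes higher (camera adjusted p = 4.24e-13; adjusted p = 0.367 with an estimated correlation). After quantile normalization it lay 0.32 above them (camera adjusted p = 1.16e-04; 2.03e-13 to 0.718 over settings). Replication-dependent histone genes moved the same way, with 5 higher and 0 lower of 11 (7 and 0 adjusted over the list alone, camera adjusted p = 9.30e-05); adjusted p = 0.688 with an estimated correlation. Their difference from other genes was 0.75, and 0.48 with the length trend removed, chosen after seeing the data (camera adjusted p = 0.0130; 1.55e-06 to 0.688 over settings). H1-2, a linker histone (GRCh38 chromosome 6, 26055740 to 26056470), went from 112 ± 26.2 to 432 ± 295 FPKM, and H2AC25 from 4.77 ± 0.572 to 9.12 ± 1.25 FPKM (adjusted p = 0.0240 and 0.0245). Histone and ribosomal protein genes have close copies and processed pseudogenes, so the division of reads is uncertain. Poly(A) selection leaves histone RNA level and polyadenylation unseparated. The calls of the 4 genes named here were lost when any 1 of the 3 control libraries was left out (adjusted p from 0.0510 for H1-2 without replicate 3 to 0.131 for RPS19 without replicate 1; 0.00852 to 0.0951 and 5.20e-04 to 0.131 over settings). They were also lost with no filter, with adjusted p from 0.0552 for H2AC25 to 0.106 for RPS19.

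**Figure D2:**
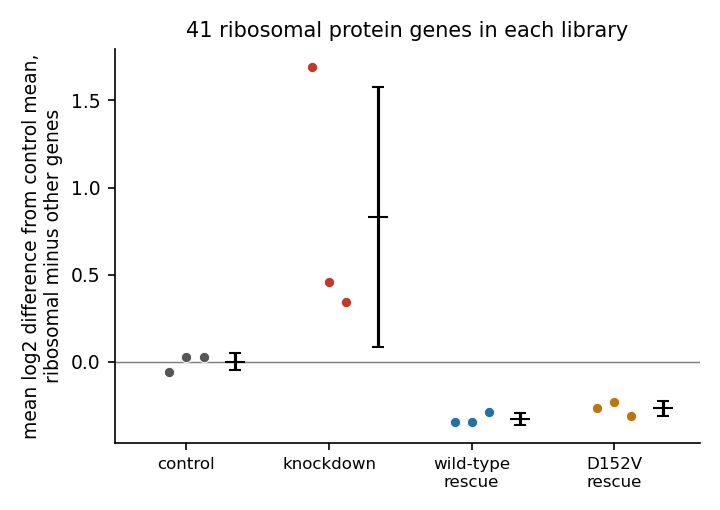
Mean log2 difference of 41 ribosomal protein genes from the control mean, minus the same mean over all other tested genes (vertical axis, log2 units), in each of the 12 libraries (points), with group mean and SD in black (n = 3). The knockdown libraries lie at 1.69, 0.46 and 0.34, and all 6 rescue libraries between -0.35 and -0.23.

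Globin transcripts were variable between knockdown libraries. No globin gene passed the test in this comparison. HBE1, the embryonic epsilon globin (GRCh38 chromosome 11, 5268345 to 5269945), stood at 876 ± 356 FPKM in control and 2049 ± 1243 in knockdown libraries. HBG2 stood at 63.3 ± 22.5 and 297 ± 317, HBG1 at 19.1 ± 8.24 and 55.1 ± 41.5 and HBZ at 587 ± 256 and 1128 ± 625 (adjusted p = 0.177, 0.0836, 0.0918 and 0.315 for the 4 genes in this order). As a set the 8 measured globins (0 of 8 changed over all genes and 0 adjusted over the list alone) lay 0.99 above other genes (camera adjusted p = 0.0448; adjusted p = 0.727 with an estimated correlation). The difference was 0.42 without MYB_KnockDown replicate 1 (camera adjusted p = 0.257; 0.00822 to 0.727 over settings). The set was also lost with a mean FPKM of at least 5, with median-ratio scaling and with the length trend removed (camera adjusted p = 0.0557, 0.0590 and 0.131). Without MYB_KnockDown replicate 2, HBE1, HBG1 and HBG2 passed as higher (adjusted p = 0.0396, 0.0236 and 0.0249; 0.0396 to 0.431, 0.0236 to 0.246 and 0.0249 to 0.218 over settings), and HBG2 also after quantile normalization (0.0483). HBG1 and HBG2 are near-identical copies, so their separate values are uncertain. The erythroid membrane and maturation list had 2 higher and 3 lower of 26 (2 and 3 adjusted over the list alone, camera adjusted p = 0.974). HEMGN, an erythroid nuclear protein, fell from 134 ± 25.0 to 61.0 ± 16.4 FPKM (adjusted p = 0.0102; lost without siRNA_Control replicate 1, adjusted p = 0.0607; 0.00563 to 0.0607 over settings), and BLVRB rose from 86.8 ± 8.67 to 179 ± 85.8 FPKM (adjusted p = 0.0343). The BLVRB call was lost when any 1 of the 3 control libraries was left out (adjusted p = 0.109, 0.123 and 0.0720) or no filter was set (0.0798; 0.00318 to 0.123 over settings). ITGA2B, the platelet integrin alpha IIb, stood at 0.995 ± 0.259 and 1.35 ± 0.545 FPKM (adjusted p = 0.465).

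No other list passed as a set. Heme synthesis and iron genes had 0 higher and 1 lower of 20 (0 and 1 adjusted over the list alone, 1 and 1 in 11 libraries, camera adjusted p = 0.647). Megakaryocyte and platelet genes had 1 higher and 0 lower of 15 (1 and 0 adjusted over the list alone, 2 and 0 in 11 libraries, camera adjusted p = 0.401). Stem and progenitor surface genes had 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone, camera adjusted p = 0.778). Among markers of other cell types, those of monocytes and granulocytes gave 1 higher and 0 lower of 6 (1 and 0 adjusted over the list alone, camera adjusted p = 0.790). Lymphoid markers gave 1 higher and 0 lower of 4 (1 and 0 adjusted over the list alone, camera adjusted p = 0.433), and fibroblast and epithelial markers 0 higher and 0 lower of 6 (2 and 0 adjusted over the list alone, 2 and 1 in 11 libraries, camera adjusted p = 0.0766). Among apoptosis regulators BCL2A1, a BCL2-family survival protein, rose from 0.215 ± 0.127 to 1.52 ± 0.492 FPKM (adjusted p = 0.00624) and BAD, a BCL2-family antagonist, from 4.44 ± 0.624 to 11.2 ± 3.09 FPKM (adjusted p = 0.00852; lost without siRNA_Control replicate 1, adjusted p = 0.0518; 0.00336 to 0.0518 over settings). That list had 2 higher and 1 lower of 17 (2 and 1 adjusted over the list alone, camera adjusted p = 0.171), and passed without MYB_KnockDown replicate 1 (camera adjusted p = 0.0432; 0.0432 to 0.688 over settings), though not with an estimated correlation there (adjusted p = 0.367). S phase genes gave 1 higher and 0 lower of 28 (0 and 0 adjusted over the list alone, 1 and 6 in 11 libraries, camera adjusted p = 0.778). Genes of G2 and M phase gave 1 higher and 1 lower of 26 (1 and 1 adjusted over the list alone, 2 and 1 in 11 libraries, camera adjusted p = 0.974), and CDK inhibitors and G1 cyclins 1 higher and 1 lower of 15 (4 and 1 adjusted over the list alone, 3 and 1 in 11 libraries, camera adjusted p = 0.974). The MYC program gave 0 higher and 2 lower of 22 (0 and 2 adjusted over the list alone, 0 and 5 in 11 libraries, camera adjusted p = 0.647), and passed as lower without MYB_KnockDown replicate 1 (camera adjusted p = 0.0103) and after quantile normalization (0.0172; 0.0103 to 0.941 over settings). Without that library the adjusted p was 0.508 with an estimated correlation. Immediate early genes gave 0 higher and 1 lower of 17 (0 and 1 adjusted over the list alone, 3 and 2 in 11 libraries, camera adjusted p = 0.778). Interferon response genes gave 1 higher and 0 lower of 14 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0605). Amino acid and ER stress genes gave 1 higher and 0 lower of 22 (0 and 0 adjusted over the list alone, 1 and 1 in 11 libraries, camera adjusted p = 0.0758). Cholesterol synthesis genes gave 0 higher and 2 lower of 23 (0 and 2 adjusted over the list alone, 1 and 2 in 11 libraries, camera adjusted p = 0.647), and hypoxia and glycolysis genes 1 higher and 1 lower of 23 (1 and 0 adjusted over the list alone, 3 and 4 in 11 libraries, camera adjusted p = 0.790). Heat shock genes gave 0 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, 0 and 1 in 11 libraries, camera adjusted p = 0.974), with a mean difference from other genes of 0.05 that became -0.26 after quantile normalization (camera adjusted p = 0.0335; 0.0335 to 0.999 over settings). Reference genes gave 0 higher and 0 lower of 14 (0 and 0 adjusted over the list alone, 2 and 2 in 11 libraries, camera adjusted p = 0.647). Median, mean and camera direction differed in sign for the monocyte, G2 and M, CDK inhibitor and heat shock lists. Of the genes in the 26 lists 63 were called. Without siRNA_Control replicates 1, 2 and 3 it was 11, 14 and 25, without MYB_KnockDown replicates 1, 2 and 3 it was 119, 112 and 106, without MYB-WT_Rescue replicate 1 it was 41 and without D152V_Rescue replicate 2 it was 37.

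The list of mitochondrial genome transcripts had 3 higher and 0 lower of 13 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0797), with a median log2 change of -0.48 and a mean of 2.66. Its 3 called members, MT-ATP8, MT-CO3 and MT-ATP6, are listed at 0 in all 9 control and rescue libraries. In MYB_KnockDown replicates 1, 2 and 3 MT-CO3 was listed at 16310, 9906 and 12230 FPKM, MT-ATP6 at 6183, 5185 and 5132 and MT-ATP8 at 18680, 39710 and 38300. The other 10 mitochondrial protein genes were above 0 in all 12 libraries. No fold change is given for the 3 genes. They are among the genes counted as changed; without the 83 tested genes listed at 0 in a whole group the count for this comparison was 1503.

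In all, 1516 of 13393 genes changed between knockdown and control (limma, adjusted p under 0.05), 528 higher and 988 lower, and 148 and 149 of them at least 2-fold. Leaving out MYB_KnockDown replicate 1 gave 2697 changed genes, 972 higher and 1725 lower, but only 64 and 87 of them at least 2-fold. They shared 1469 of the 1516 genes in the same direction and none in the opposite. The share of higher calls was 34.8%, and 45.5% after quantile normalization (888 higher, 1064 lower). It was 46.9% after median-ratio scaling (700 higher, 794 lower) and 45.9% with the length trend removed (615 higher, 726 lower). The count was 173, 211 and 429 without siRNA_Control replicates 1, 2 and 3, and 2592 and 2384 without MYB_KnockDown replicates 2 and 3. Through the shared spread the count was also 976 without MYB-WT_Rescue replicate 1 and 984 and 904 without D152V_Rescue replicates 1 and 2. Fitted on the 6 compared libraries alone, 16 genes passed, 4 higher and 12 lower. Residual SD was 0.323 to 0.566 in knockdown libraries and 0.161 to 0.223 elsewhere. The shared spread can make p-values too small for knockdown comparisons and too large for others. The count was 738 with no filter, 187 at an adjusted p under 0.01 and 3581 with library weights.

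**Figure D3:**
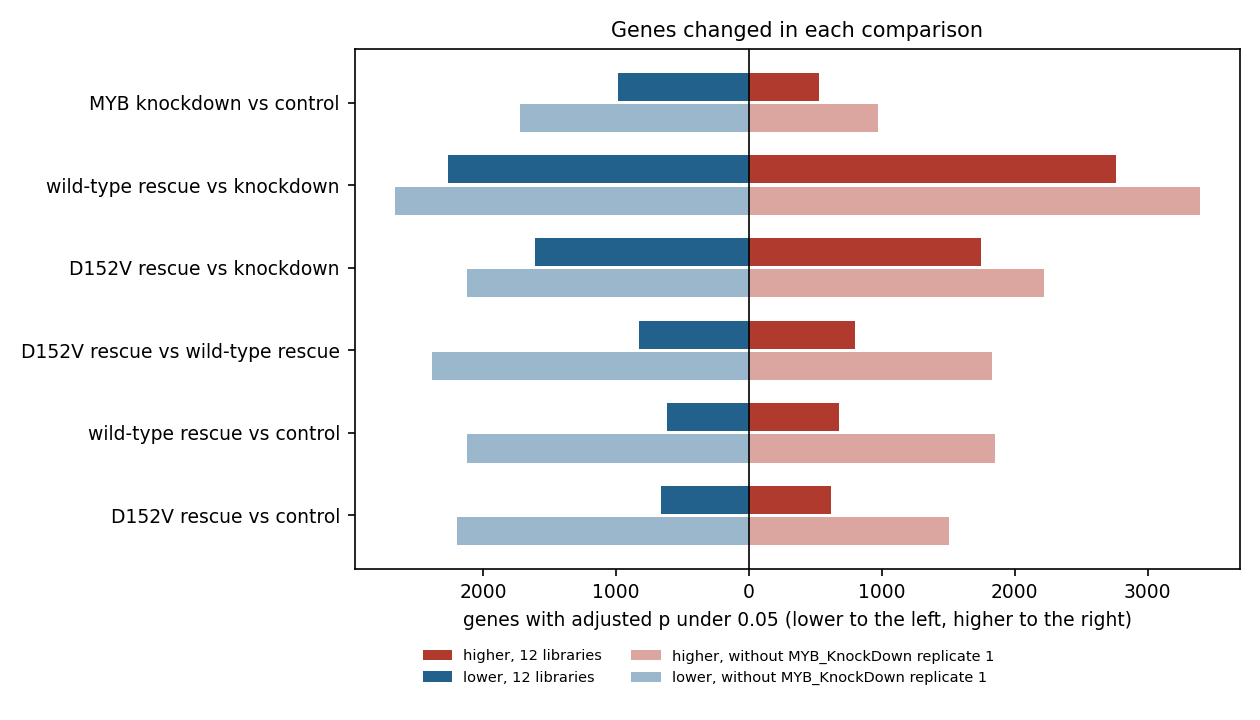
Number of genes with a limma adjusted p under 0.05 in each of 6 comparisons (horizontal axis, lower genes to the left of 0 and higher genes to the right), from the 12 libraries (dark bars) and without MYB_KnockDown replicate 1 (pale bars). The wild-type rescue against the knockdown has the most calls, 2765 higher and 2266 lower.

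The wild-type rescue line was compared with the knockdown to ask which transcripts differ when tagged wild-type MYB is present under the same siRNA. MYC rose from 96.7 ± 23.4 to 185 ± 8.0 FPKM and LMO2 from 12.3 ± 2.27 to 26.9 ± 2.09 FPKM (log2 changes 0.96 and 1.09, limma adjusted p = 0.00262 and 0.00106; SD, n = 3). KIT rose from 3.24 ± 1.39 to 8.81 ± 1.59 FPKM, MYADM from 13.3 ± 5.69 to 40.3 ± 9.05 FPKM and CDK6, a G1 kinase, from 18.2 ± 2.497 to 42.6 ± 1.30 FPKM (log2 changes 1.26, 1.59 and 1.19, adjusted p = 0.00438, 0.00221 and 8.00e-05). RUNX1 rose from 12.9 ± 1.40 to 24.4 ± 5.11 FPKM, while SPI1, the myeloid factor PU.1, fell from 23.7 ± 4.98 to 11.5 ± 2.37 FPKM (adjusted p = 0.00469 and 0.00714). HBE1 fell from 2049 ± 1243 to 54.2 ± 16.03 FPKM (log2 change -5.03, adjusted p = 9.90e-05), below the control level of 876 ± 356. These 8 genes passed in every setting computed for single genes.

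The erythroid membrane gene GYPB and the heme synthesis gene ALAS2 fell in this line, while the erythroid list as a whole went both ways. GYPB fell from 326 ± 102 to 67.7 ± 18.4 FPKM (log2 change -2.23, adjusted p = 0.00100), with a value that is uncertain because reads can be shared within its gene family. ALAS2 fell from 85.7 ± 21.1 to 41.1 ± 8.27 FPKM (adjusted p = 0.00441). The erythroid list had 6 higher and 7 lower of 26 (6 and 7 adjusted over the list alone, camera adjusted p = 0.876), with a median change of 0.07 and a mean of -0.15. Globins had 0 higher and 5 lower of 8 (0 and 6 adjusted over the list alone, 1 and 4 in 11 libraries, camera adjusted p = 0.0128); adjusted p = 0.692 with an estimated correlation. The globin set no longer passed without MYB_KnockDown replicate 1 (camera adjusted p = 0.0755; 0.00305 to 0.692 over settings). HBG1 was 17.4 ± 5.60 FPKM here (adjusted p = 0.0383), and HBG2 and HBZ did not pass (adjusted p = 0.0566 and 0.353). The HBG1 call was lost without MYB_KnockDown replicates 1 or 3 or MYB-WT_Rescue replicates 1 or 2 (adjusted p = 0.0851, 0.0543, 0.108 and 0.114) or with no filter (0.0927; 0.00646 to 0.114 over settings), and HBG2 passed without MYB_KnockDown replicate 2 (0.0108) or after quantile normalization (0.0350; 0.0108 to 0.154 over settings). Ribosomal protein genes fell in 29 of 41 cases (32 adjusted over the list alone), with a set difference of -1.16 (camera adjusted p = 1.78e-11; adjusted p = 0.692 with an estimated correlation) that was -0.73 without MYB_KnockDown replicate 1 and -0.48 after quantile normalization (camera adjusted p = 8.24e-05; 9.10e-15 to 0.692 over settings). Histones had 0 higher and 7 lower of 11 (0 and 8 adjusted over the list alone, camera adjusted p = 0.00440); adjusted p = 0.692 with an estimated correlation. The histone set did not pass with the length trend removed (camera adjusted p = 0.133; 2.38e-04 to 0.692 over settings).

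MYB targets from the literature had 6 higher and 0 lower of 17 (6 and 0 adjusted over the list alone, 7 and 2 in 11 libraries, camera adjusted p = 0.179), and hematopoietic transcription factors 9 higher and 5 lower of 25 (9 and 6 adjusted over the list alone, 9 and 8 in 11 libraries, camera adjusted p = 0.535). GATA1 fell from 125 ± 8.95 to 91.0 ± 12.7 FPKM (adjusted p = 0.0294; 0.0707, 0.0856 and 0.111 without MYB_KnockDown replicate 3 and MYB-WT_Rescue replicates 1 and 2, and 0.193 after quantile normalization; 0.00652 to 0.193 over settings). GATA2, KLF1 and TAL1 did not pass (adjusted p = 0.275, 0.757 and 0.0555), though TAL1 passed without MYB_KnockDown replicate 1 (5.84e-04) or with median-ratio scaling (0.0338; 5.84e-04 to 0.148 over settings). The largest increases among the genes named by the fixed rule were in C12orf75 (0.0732 ± 0.127 to 22.1 ± 4.91 FPKM), CASP4 (0.291 ± 0.286 to 15.8 ± 5.44), CPVL (1.26 ± 0.197 to 21.8 ± 1.75), CDH18 (1.43 ± 0.773 to 22.6 ± 4.37), MUC19 (3.44 ± 1.498 to 40.1 ± 8.75) and SLC16A9 (1.61 ± 0.372 to 18.8 ± 4.55). ALDH1A1, a retinaldehyde dehydrogenase, fell from 59.8 ± 11.97 to 3.86 ± 1.66 FPKM and the globin pseudogene HBBP1 from 71.2 ± 62.5 to 5.07 ± 4.31. The control line held 0.217, 0.645, 1.142, 2.15, 2.27 and 2.90 FPKM of those 6 genes and 70.6 FPKM of ALDH1A1. In all, 5031 genes changed, 2765 higher and 2266 lower, and 6055 without MYB_KnockDown replicate 1 (4646 shared in direction). The count was 3194 without MYB-WT_Rescue replicate 2, 1689 on the 6 compared libraries alone and 2543 at an adjusted p under 0.01. Of the genes in the lists 180 were called, and 119 without MYB-WT_Rescue replicate 2.

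The D152V rescue line was compared with the knockdown in the same way. MYADM rose from 13.3 ± 5.69 to 28.4 ± 6.999 FPKM and CDK6 from 18.2 ± 2.497 to 27.3 ± 1.48 FPKM (log2 changes 1.09 and 0.57, limma adjusted p = 0.0219 and 0.00812; SD, n = 3). MYC stood at 117 ± 17.5 FPKM against 96.7 ± 23.4, KIT at 3.54 ± 0.509 against 3.24 ± 1.39, LMO2 at 11.02 ± 1.70 against 12.3 ± 2.27 and RUNX1 at 12.8 ± 2.80 against 12.9 ± 1.40, none of which passed (adjusted p = 0.242, 0.689, 0.570 and 0.924). SPI1 fell from 23.7 ± 4.98 to 7.35 ± 1.55 FPKM and TAL1 from 51.7 ± 9.08 to 34.5 ± 1.47 FPKM (log2 changes -1.56 and -0.56, adjusted p = 0.00124 and 0.0135). HEMGN rose from 61.0 ± 16.4 to 134 ± 19.6 FPKM and SOX6, a repressor of embryonic globin genes, from 1.42 ± 0.768 to 6.29 ± 1.42 FPKM, while HBE1 fell from 2049 ± 1243 to 249 ± 155 FPKM (log2 changes 1.15, 1.62 and -2.98, adjusted p = 0.00363, 8.80e-04 and 0.00353). The MYADM call was lost without D152V_Rescue replicate 1 or 2 (adjusted p = 0.0803 and 0.0724) and with no filter (0.0518; 0.00857 to 0.0803 over settings).

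Myeloid markers were lower in this line than in the knockdown. AIF1, a macrophage calcium-binding protein, fell from 12.9 ± 7.20 to 0.410 ± 0.162 FPKM, LYZ, lysozyme, from 19.7 ± 10.8 to 4.20 ± 0.813 FPKM and CD33, a myeloid surface lectin, from 23.3 ± 3.13 to 10.6 ± 1.00 FPKM (log2 changes -3.19, -1.82 and -1.06, adjusted p = 5.48e-05, 0.00732 and 9.31e-04). The list of monocyte and granulocyte markers had 0 higher and 4 lower of 6 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0416); adjusted p = 0.755 with an estimated correlation. K-562 cells expressed these markers in the control group too, at 3.65 ± 0.524, 20.9 ± 4.66 and 20.0 ± 3.50 FPKM. Fibroblast and epithelial markers had 0 higher and 3 lower of 6 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0416); adjusted p = 0.951 with an estimated correlation. Their 3 called members were the keratins KRT8 and KRT18 and the collagen COL1A2, at 226 ± 37.9, 129 ± 14.4 and 0.145 ± 0.181 FPKM against 792 ± 630.5, 350.5 ± 226 and 2.34 ± 1.141 in the knockdown. KRT8 and KRT18 were lost without D152V_Rescue replicate 1 (adjusted p = 0.0688 and 0.0655) and KRT18 also without replicate 3 (0.0553; 0.00139 to 0.0688 and 0.00224 to 0.0655 over settings). The marker sets for monocytes and for fibroblasts also missed the threshold when genes with a mean FPKM under 5 were left out (camera adjusted p = 0.0616 and 0.136; 0.00257 to 0.755 and 0.0342 to 0.951 over settings). The monocyte set missed it with the length trend removed (0.105) and the fibroblast set with no filter (0.513). With no filter the differences from other genes went from -1.14 to -0.41 for the monocyte set (camera adjusted p = 0.00257) and from -0.97 to -0.36 for the fibroblast set.

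Amino acid and ER stress genes had 0 higher and 5 lower of 22 (0 and 6 adjusted over the list alone, camera adjusted p = 0.0166); adjusted p = 0.951 with an estimated correlation, and camera adjusted p = 0.110 after quantile normalization (0.00270 to 0.951 over settings). PSAT1, an enzyme of serine synthesis, fell from 33.9 ± 6.57 to 15.8 ± 1.55 FPKM (adjusted p = 0.00108). Ribosomal protein genes had 0 higher and 28 lower of 41 (0 and 32 adjusted over the list alone, camera adjusted p = 4.47e-13); adjusted p = 0.951 with an estimated correlation. Their set difference of -1.10 became -0.67 without MYB_KnockDown replicate 1 and -0.45 after quantile normalization (camera adjusted p = 3.55e-06; 3.53e-18 to 0.951 over settings). Globins had 0 higher and 1 lower of 8 (0 and 1 adjusted over the list alone, 1 and 1 in 11 libraries, camera adjusted p = 0.178), and histones 1 higher and 1 lower of 11 (2 and 1 adjusted over the list alone, camera adjusted p = 0.857). Hematopoietic transcription factors had 5 higher and 4 lower of 25 (5 and 4 adjusted over the list alone, 6 and 7 in 11 libraries, camera adjusted p = 0.857). MYB targets had 2 higher and 1 lower of 17 (2 and 1 adjusted over the list alone, 3 and 2 in 11 libraries, camera adjusted p = 1.000), and their median, mean and camera direction differed in sign. The largest increases under the fixed rule were in RBPMS2 (0.843 ± 0.317 to 45.6 ± 2.23 FPKM), TPD52 (0.367 ± 0.128 to 26.7 ± 1.61), TUBA3C (1.67 ± 0.267 to 49.1 ± 10.1), ENAH (0.273 ± 0.137 to 20.9 ± 4.20), PAK1 (1.40 ± 0.183 to 15.3 ± 0.275) and IFI16 (12.6 ± 2.37 to 74.3 ± 9.14). Apart from MT-ATP8, MT-CO3 and MT-ATP6, listed at 0, the largest decreases were in IFITM3, an antiviral membrane protein (82.3 ± 5.80 to 1.54 ± 0.226 FPKM), SSX3 (31.8 ± 2.92 to 0.105 ± 0.110) and the imprinted noncoding RNA H19 (47.2 ± 22.9 to 0.815 ± 0.139). In all, 3355 genes changed, 1745 higher and 1610 lower, and 4346 without MYB_KnockDown replicate 1 (3089 shared in direction). The count was 1829, 1639 and 1820 without D152V_Rescue replicates 1, 2 and 3. It was 548 on the 6 compared libraries alone, 1129 at an adjusted p under 0.01 and 5116 with library weights. Of the genes in the lists 130 were called, and 74, 74 and 84 without D152V_Rescue replicates 1, 2 and 3.

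Knockdown genes moved back were then counted. Of the 988 genes lowered by the knockdown, the wild-type rescue raised 781 again (79.0%) and the D152V rescue 517 (52.3%), where independent lists of these sizes would share 204 and 129 genes. Of the 528 raised genes, 452 (85.6%) and 349 (66.1%) were lowered again, against 89.3 and 63.5 for independent lists. Against control, 77 of the lowered genes still passed as lower in the wild-type and 177 in the D152V rescue. Of the raised genes 20 and 63 still passed as higher. In all, 1233 (81.3%) and 866 (57.1%) knockdown genes moved back, and 2115 (78.4%) and 1512 (56.1%) without MYB_KnockDown replicate 1. The knockdown and rescue changes correlated at r = -0.773 (wild-type) and -0.712 (D152V) over all 13393 genes, which are not independent replicates. Both comparisons use the same knockdown libraries, whose residual SD was wider. In 40 simulations with 1 pooled spread, unchanged groups gave r = -0.495 and -0.497 and covariances of -0.0301 and -0.0304 against -0.285 and -0.237 observed; rescues left at the knockdown level moved back at most 0 and 1 genes. These understate the shared part, with 3384 knockdown calls against 1516. In 100 simulations with each group's own spread, added after seeing the data, mean r was -0.728 and -0.727 and the mean covariance -0.0864 and -0.0854 (observed minus simulated -0.199 and -0.151). There r was as low as observed 54 and 61 times and the covariance 7 and 10 times, and as many genes moved back 5 and 4 times. The shared libraries alone can thus give the observed r. With different knockdown libraries for the 2 changes, 1 against 2 in all 6 ways (also added then), the covariance was -0.229 to -0.174 for the wild-type and -0.176 to -0.125 for the D152V rescue, and r -0.541 to -0.382 and -0.454 to -0.334. Between 17.2% (of 2387) and 88.5% (of 26) of knockdown genes moved back in the wild-type rescue. In the D152V rescue 2.64% (of 2387) to 60.8% (of 2696) did, and all shares were above independent lists. Without siRNA_Control replicates 1, 2 and 3, 142, 173 and 358 genes moved back in the wild-type and 94, 121 and 262 in the D152V rescue, and without MYB_KnockDown replicates 2 and 3, 2067 and 2003 against 1543 and 1639. Without MYB-WT_Rescue replicates 1 and 2 the wild-type count was 717 and 795, and without D152V_Rescue replicates 1 and 2 it was 790 and 727. The D152V count was 539 without MYB-WT_Rescue replicate 1 and 420, 355 and 474 without D152V_Rescue replicates 1, 2 and 3. The 2 counts were 566 and 409 with no filter, 143 and 76 at an adjusted p under 0.01, and 2643 and 2049 with library weights.

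**Figure D4:**
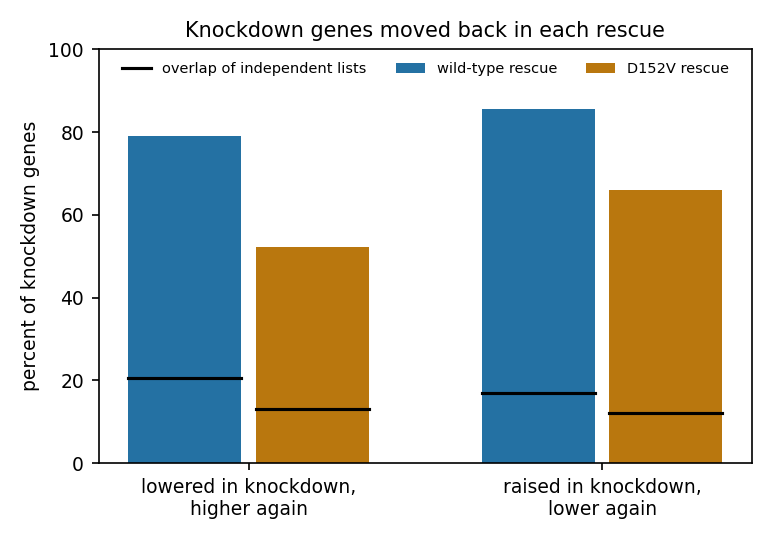
Share of knockdown genes that passed the test in the opposite direction in each rescue against the knockdown (vertical axis, percent), for the 988 lowered and the 528 raised genes. Bars are the wild-type and D152V rescue, and black lines give the share that independent lists would have; the wild-type bars reach 79.0% and 85.6% and the D152V bars 52.3% and 66.1%.

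The D152V rescue was compared with the wild-type rescue to ask how the 2 forms differ under the same siRNA. LMO2 was 11.02 ± 1.70 FPKM with D152V and 26.9 ± 2.09 with wild-type MYB (log2 difference -1.22, SE 0.17, limma adjusted p = 7.36e-04; SD, n = 3). RUNX1 was 12.8 ± 2.80 against 24.4 ± 5.11 FPKM and CDK6 27.3 ± 1.48 against 42.6 ± 1.30 FPKM, both lower with D152V (log2 differences -0.88 and -0.62, adjusted p = 0.00832 and 0.00560). KIT was 3.54 ± 0.509 against 8.81 ± 1.59 FPKM and MYC 117 ± 17.5 against 185 ± 8.0 FPKM (log2 differences -1.11 and -0.66, adjusted p = 0.0178 and 0.0351). The KIT call was lost without MYB-WT_Rescue replicate 1 or D152V_Rescue replicates 2 or 3, and the MYC call when any 1 of the 6 rescue libraries was left out (adjusted p up to 0.0773 for KIT and 0.141 for MYC; 0.00146 to 0.0773 and 0.00144 to 0.141 over settings). The MYC call was also lost with no filter (0.0593) and after quantile normalization (0.121). MYADM stood at 28.4 ± 6.999 and 40.3 ± 9.05 FPKM and did not pass (adjusted p = 0.339).

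**Figure D5:**
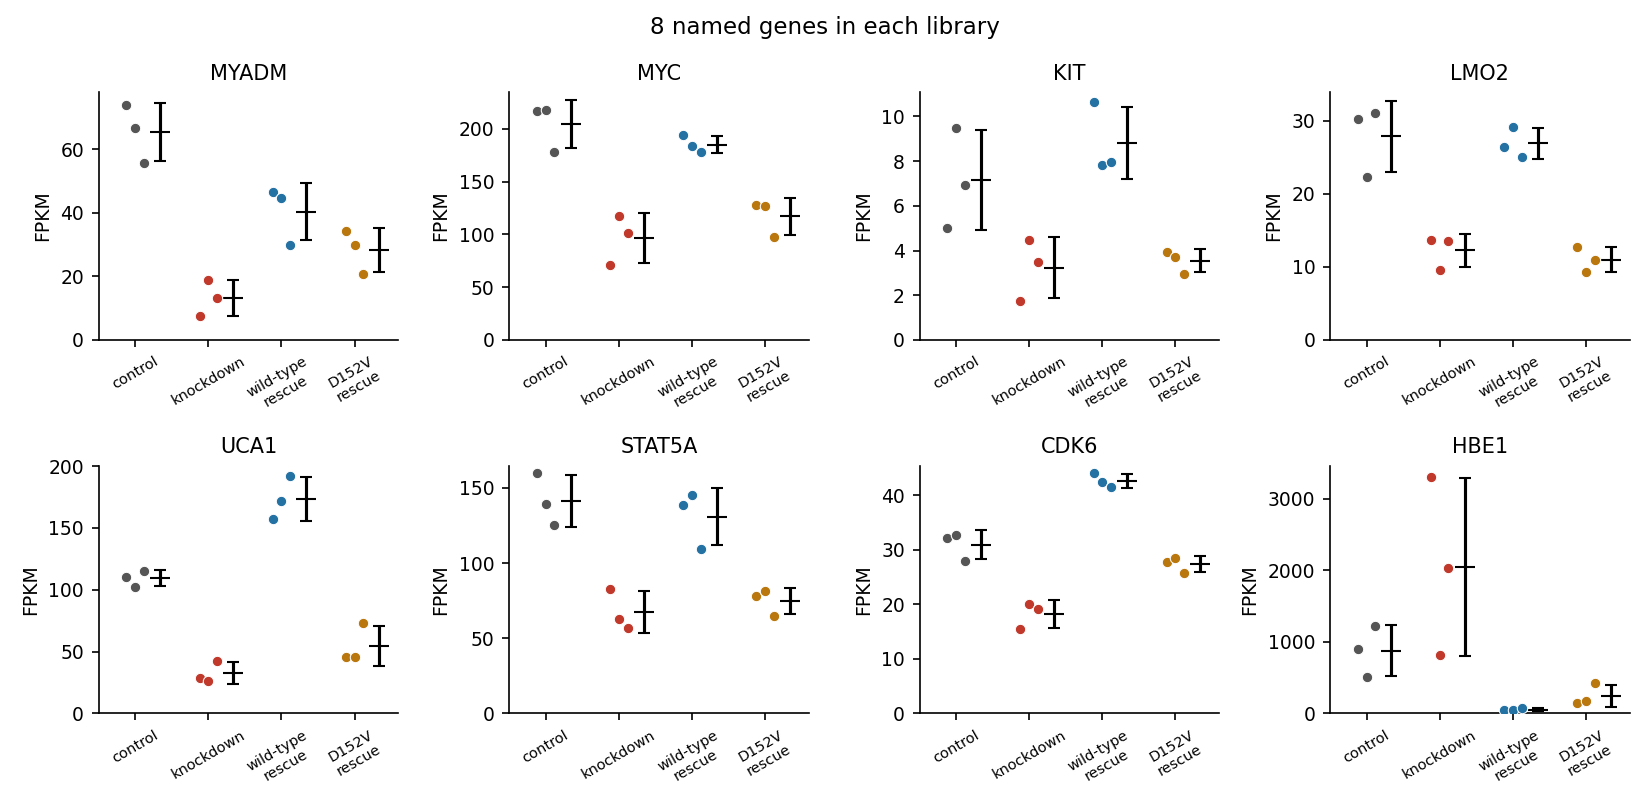
FPKM (vertical axes, each starting at 0) of MYADM, MYC, KIT, LMO2, UCA1, STAT5A, CDK6 and HBE1 in each of the 12 libraries (points) of the 4 groups, with group mean and SD in black (n = 3). LMO2 averages 27.9 FPKM in the control, 12.3 in the knockdown, 26.9 in the wild-type rescue and 11.02 in the D152V rescue.

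Erythroid genes differed between the rescue lines in both directions. HBE1 was 249 ± 155 FPKM with D152V and 54.2 ± 16.03 with wild-type MYB, and ALAS2 103 ± 21.4 against 41.1 ± 8.27 FPKM (log2 differences 2.05 and 1.31, adjusted p = 0.0263 and 0.00214). SOX6 and HEMGN were higher with D152V (log2 differences 2.07 and 0.94, adjusted p = 1.01e-04 and 0.0108), while CD36 and the band 3 gene SLC4A1 were lower (-1.73 and -1.13, adjusted p = 5.92e-05 and 0.00560). The HBE1 call was lost without MYB-WT_Rescue replicates 1 or 2 or D152V_Rescue replicates 2 or 3, and the HEMGN call without MYB-WT_Rescue replicate 1 or D152V_Rescue replicate 3 (adjusted p up to 0.109 for HBE1, 0.0614 with no filter, and 0.0527 for HEMGN; 0.00560 to 0.109 and 0.00284 to 0.0527 over settings). The erythroid list had 4 higher and 2 lower of 26 (5 and 2 adjusted over the list alone, 8 and 3 in 11 libraries, camera adjusted p = 0.138), and globins 1 higher and 0 lower of 8 (3 and 0 adjusted over the list alone, 3 and 0 in 11 libraries, camera adjusted p = 0.105). Heme genes had 3 higher and 1 lower of 20 (5 and 1 adjusted over the list alone, 6 and 3 in 11 libraries, camera adjusted p = 0.245), and hematopoietic transcription factors 1 higher and 4 lower of 25 (3 and 4 adjusted over the list alone, 4 and 8 in 11 libraries, camera adjusted p = 0.380). GATA1, GATA2, KLF1, TAL1, SPI1, CEBPB, HBG1, HBG2, HBZ and ITGA2B did not pass, with adjusted p values from 0.0691 for GATA1 to 0.937 for ITGA2B. GATA1 passed without MYB_KnockDown replicate 1 or MYB-WT_Rescue replicate 3 (adjusted p = 0.0203 and 0.0489) or with median-ratio scaling (0.0485), and HBZ without the same libraries (0.0334 and 0.0377). Over settings these adjusted p values ran from 0.0138 to 0.244 for GATA1, 0.00242 to 0.276 for HBZ and 0.00422 to 0.411 for SPI1. With the replicate number as a block GATA1 and HBZ passed as higher with D152V and SPI1 as lower (log2 differences 0.45, 1.68 and -0.58, adjusted p = 0.0138, 0.00242 and 0.00422). The globin set lay 0.85 above other genes and passed with the block (camera adjusted p = 0.0335; adjusted p = 0.535 with an estimated correlation). It also passed with a mean FPKM of at least 5 (0.0375) and without MYB_KnockDown replicate 1 (0.0458, but adjusted p = 0.668 with an estimated correlation; 0.0335 to 0.719 over settings).

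Heat shock genes were lower with D152V, with 0 higher and 8 lower of 13 (0 and 9 adjusted over the list alone, camera adjusted p = 2.25e-04); adjusted p = 0.667 with an estimated correlation. DNAJA1, a chaperone of the HSP40 family, was 244 ± 2.63 against 429.7 ± 27.7 FPKM and DNAJB1 52.9 ± 2.45 against 84.0 ± 11.4 FPKM (adjusted p = 0.00186 and 0.00682). HSPA1A and HSPA1B, near-identical genes for inducible HSP70, were lower by log2 differences of -1.20 and -0.86 (adjusted p = 0.00807 and 0.00942). Amino acid and ER stress genes had 0 higher and 4 lower of 22 (0 and 4 adjusted over the list alone, 0 and 10 in 11 libraries, camera adjusted p = 0.0110); adjusted p = 0.667 with an estimated correlation. Its 4 called members were HERPUD1, SLC7A11, PSAT1 and DNAJB9 (log2 differences -0.90, -0.79, -0.78 and -0.73), HERPUD1 being lost without D152V_Rescue replicate 2 (adjusted p = 0.0536; 0.00136 to 0.0536 over settings). Histones had 4 higher and 0 lower of 11 (6 and 0 adjusted over the list alone, 8 and 0 in 11 libraries, camera adjusted p = 2.25e-04); adjusted p = 0.667 with an estimated correlation, with H2BC21 at 66.7 ± 20.4 against 23.6 ± 4.17 FPKM and H2BC12 at 694 ± 156 against 374 ± 44.1 FPKM (adjusted p = 0.00474 and 0.00944). MYB targets from the literature had 0 higher and 5 lower of 17 (1 and 7 adjusted over the list alone, 1 and 7 in 11 libraries, camera adjusted p = 0.0542). Apoptosis regulators had 4 higher and 3 lower of 17 (4 and 3 adjusted over the list alone, camera adjusted p = 0.281), with FAS and BCL2L1 higher and BCL2L11 lower (log2 differences 1.25, 0.87 and -0.94, adjusted p = 2.13e-04, 5.91e-04 and 0.00176).

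The largest differences between the rescue lines under the fixed rule were in genes not used as hematopoietic markers here. TUBA3C, TPD52, CTAG2, ENAH, RBPMS2 and ABRACL were higher with D152V by 5.35, 4.52, 4.39, 3.92, 3.70 and 3.65 on the log2 scale. H19, MUC19, CPVL, ARHGAP15, CRYAB and CDH18 differed by -5.67, -4.86, -4.36, -3.88, -3.70 and -3.70. In all, 1627 genes differed, 798 higher and 829 lower with D152V. Without MYB_KnockDown replicate 1, which enters this comparison only through the shared spread, 4209 differed, among them all 1627. The count was 1020 without MYB-WT_Rescue replicate 2 and 1078 and 1032 without D152V_Rescue replicates 1 and 2. On the 6 compared libraries alone it was 3275, with a mean FPKM of at least 5 it was 869, at an adjusted p under 0.01 it was 858 and with library weights 4366. Of the genes in the lists 72 were called, 164 without MYB_KnockDown replicate 1, 47 and 46 without MYB-WT_Rescue replicates 1 and 2, and 47 and 44 without D152V_Rescue replicates 2 and 3.

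Genes that also changed with the knockdown mostly differed in the knockdown's direction. Of the 988 genes lowered by the knockdown, 156 were lower and 19 higher with D152V than with wild-type MYB, where independent lists would share 61.2 and 58.9. Of the 528 raised genes, 83 were higher and 9 lower, against 31.5 and 32.7. The 2 comparisons share no library, and 239 of the 267 genes called in both (89.5%, exact 95% interval 85.2% to 92.9%, with genes treated as independent) went the same way. As sets the lowered and raised genes had median differences of -0.23 and 0.20, and neither passed camera with an estimated correlation (p = 0.250 and 0.297; 0.0815 and 0.115 without MYB_KnockDown replicate 1). The number called in both was 1178 without MYB_KnockDown replicate 1, of which 1010 (85.7%) went the same way. It was 54, 65 and 99 without siRNA_Control replicates 1, 2 and 3, 122 and 125 without MYB-WT_Rescue replicates 1 and 2, and 124, 105 and 126 without D152V_Rescue replicates 1, 2 and 3. It was 154 with no filter, 32 at an adjusted p under 0.01 and 1449 with library weights. A further 1360 of the 1627 genes (83.6%) did not pass in the knockdown comparison.

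Each rescue line was also compared with the control line, which differs from it in the stable construct as well as in the siRNA. Of 191 named genes tested, 47 differed from control in the wild-type rescue and 60 in the D152V rescue; the genes given here were chosen from them after their values were seen. IFITM3 was 6.63 ± 0.329 FPKM in the wild-type and 1.54 ± 0.226 in the D152V rescue against 71.1 ± 10.5 in control (limma adjusted p = 1.98e-07 and 5.42e-09). HBE1 lay below control in both lines (log2 differences -3.94 and -1.89, adjusted p = 9.98e-04 and 0.0458). LMO2, MYC, STAT5A and UCA1 lay below control in the D152V rescue (log2 differences -1.26, -0.80, -0.91 and -1.03, adjusted p = 9.16e-04, 0.0169, 0.00623 and 0.00907). In the wild-type rescue the same 4 genes did not pass (adjusted p = 0.937, 0.727, 0.764 and 0.0730), though UCA1 passed as higher without MYB_KnockDown replicate 1 (0.02503) and after quantile normalization (0.0411; 0.0186 to 0.205 over settings). In the D152V rescue the HBE1 call was lost without siRNA_Control replicates 1, 2 or 3 or D152V_Rescue replicates 1 or 2 (adjusted p = 0.140, 0.0516, 0.167, 0.160 and 0.156), with no filter (0.105) and with a mean FPKM of at least 5 (0.0563; 0.00994 to 0.167 over settings). The MYC call was lost there without siRNA_Control replicates 1 or 2 or D152V_Rescue replicate 3 (adjusted p = 0.0735, 0.0774 and 0.0833) and after quantile normalization (0.0919; 5.30e-04 to 0.0919 over settings). In all, 1289 genes differed between wild-type rescue and control (675 higher, 614 lower) and 1279 between D152V rescue and control (618 higher, 661 lower). The counts were 3973 and 3706 without MYB_KnockDown replicate 1, and every compared library moved a count by over 1.5 times when left out. The wild-type count was 696, 682 and 720 without siRNA_Control replicates 1, 2 and 3 and 858, 702 and 763 without MYB-WT_Rescue replicates 1, 2 and 3. The D152V count was 780, 725 and 782 without the same controls and 826, 813 and 791 without D152V_Rescue replicates 1, 2 and 3. The wild-type and D152V counts were 3512 and 3575 on the 6 compared libraries alone, 710 and 699 with a mean FPKM of at least 5, 560 and 622 at an adjusted p under 0.01, and 4090 and 4542 with library weights.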

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

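The 2 tests of the difference between the rescue lines weighed here were set out before their results were seen, except that values without MYB_KnockDown replicate 1, and the weight given to correlated genes, were chosen for this comparison after seeing the data.

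Against the knockdown, the change of 1627 genes differed between the 2 rescue lines by a direct test, and 99 genes were called in opposite directions. Among the genes fixed in advance, the D152V minus wild-type difference was -0.44 for MYB, -0.66 for MYC, -1.11 for KIT, -1.22 for LMO2, -0.88 for RUNX1 and 2.05 for HBE1 on the log2 scale. The MYB call was lost in 13 of 14 other settings, the replicate block among them. Among gene lists, the mean minus that of other genes was -0.332 for amino acid and ER stress, -0.494 for heat shock and 0.725 for replication-dependent histones, each lost with an estimated correlation. Of the 99 genes, 41 were higher in the wild-type and lower in the D152V line than in the knockdown and 58 the reverse.

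The design gives MYB form as the biological explanation, set against differences between the stable lines and less MYB transcript in the D152V line. Of the 267 genes called here and in the knockdown, 89.5% went the knockdown's way, past a bound set beforehand that was too loose because it took genes as independent: the genes lowered and raised by the knockdown had estimated correlations of 0.308 and 0.376, and neither set passed with them (camera p = 0.250 and 0.297; correlations of 0.125 and 0.154 and p = 0.0815 and 0.115 without MYB_KnockDown replicate 1). No rescue line was given the control siRNA, so line differences stay open for these and the other 1360 genes (83.6%). The wild-type rescue differed from control in 1289 genes, with MYB at 103.4% of control but another siRNA. Between knockdown (0) and wild-type rescue (1), the D152V line lay at 0.673 over knockdown-lowered genes and at 0.779 for MYB. The difference of -0.106 ran from -0.222 without siRNA_Control replicate 1 to -0.019 without MYB_KnockDown replicate 3. Choosing genes by the same knockdown libraries can draw 0.673 toward 1. Less transcript and an altered protein thus cannot be told apart here, and each may contribute.

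The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. In each of the 6 comparisons only the real split gave so many calls. The counts were 1516, 5031, 3355, 1627, 1289 and 1279 in the order of the plot of gene counts, and other splits gave at most 1. Between the rescue lines, where numbers pair the libraries, the 3 other splits that part all 3 pairs gave 0 calls. The 6 remaining splits each part 1 pair and gave at most 1. Splits that mix groups also put the group difference into the shared spread.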

How the results depend on the processing

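Library weights and removal of zeros or of the length trend (alone or with the block) were chosen after seeing the data. So were lists and rescue line genes without MYB_KnockDown replicate 1 and counts without libraries of groups not compared. All others were planned. MYB stayed lower in the knockdown in every setting run (-1.96 in the main fit, -2.05 to -1.86 with each library left out). Depth is unknown, so precision rests on 3 libraries a group. No named gene reversed; of the called named genes, 10 of 39 in the knockdown, 71 of 100 in the wild-type rescue, 51 of 87 in the D152V rescue and 42 of 59 in the comparison of the rescue lines kept their call in all settings. In each of the first 3 comparisons, 3 of the kept genes are the mitochondrial genes listed at 0 outside the knockdown. Total counts stayed within 1.5 times of their value under every scaling, the pseudocount, robust moderation, and removal of zeros or of the length trend. Quantile normalization took higher knockdown calls from 528 to 888. Apart from settings that test other genes, use fewer libraries or a stricter threshold, the cause of a change was not tested.

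With no filter the knockdown count was 738, and 566, 409 and 154 knockdown genes moved back with wild-type MYB, moved back with D152V and differed between the rescue lines. With a mean FPKM of at least 5 the rescue lines differed in 869 genes, and differed from control in 710 (wild-type) and 699 (D152V). At an adjusted p under 0.01 the 6 counts were 187, 2543, 1129, 858, 560 and 622, in the order of the plot of gene counts, and the 3 counts of knockdown genes 143, 76 and 32. With only the 6 libraries compared they were 16, 1689, 548, 3275, 3512 and 3575. Library weights gave 3581 for the knockdown, 5116 for the D152V rescue, 4366 between the rescue lines, 4090 and 4542 against control, and 2643, 2049 and 1449 for knockdown genes. With each library left out the counts ran from 173 to 2697, 3194 to 6055, 1639 to 4389, 1020 to 4209, 682 to 3973 and 725 to 3706, and those of knockdown genes from 142 to 2115, 94 to 1639 and 54 to 1178. The correlation of knockdown and rescue changes was -0.710, -0.809 and -0.701 (wild-type) with a pseudocount of 0.1, a mean FPKM of at least 5 and library weights, and -0.647 and -0.591 (D152V) with the first and last. With each library left out it ran from -0.825 to -0.688 and from -0.788 to -0.582.

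With an estimated correlation between genes every set call was lost, at unchanged mean differences from other genes: in the knockdown comparison 0.988 for globins, 0.831 for ribosomal proteins and 0.752 for histones, in the wild-type rescue comparison -1.818 for globins, -1.159 for ribosomal proteins and -0.788 for histones, in the D152V rescue comparison -1.142 for monocyte markers, -0.968 for fibroblast markers, -1.098 for ribosomal proteins and -0.389 for amino acid and ER stress, in the rescue line comparison -0.332 for amino acid and ER stress, -0.494 for heat shock and 0.725 for histones. With a pseudocount of 0.1 transcription factors (-0.33) and interferon response (0.581) newly passed in the knockdown, and MYB targets (-0.342) between the rescue lines. With no filter fibroblast markers no longer passed in the D152V rescue (-0.36). There, these sets newly passed: in the knockdown comparison -0.275 for MYB targets and -0.255 for MYB cofactors, in the wild-type rescue comparison 0.276 for MYB targets, -0.279 for monocyte markers, -0.228 for S phase, 0.274 for heat shock, -0.324 for cholesterol synthesis, -0.272 for hypoxia and glycolysis, 0.294 for MYB cofactors and -2.801 for mitochondrial genes, in the rescue line comparison -0.211 for MYB targets. The mitochondrial value rests on the 3 genes listed at 0 (main fit median 0.264). With a mean FPKM of at least 5 globins no longer passed in the knockdown (1.001). Nor did monocyte and fibroblast markers in the D152V rescue (-0.996 and -1.029). There, these sets newly passed: in the rescue line comparison -0.413 for MYB targets, 0.863 for globins and 0.403 for erythroid genes. With quantile normalization amino acid and ER stress no longer passed in the D152V rescue (-0.288). There, these sets newly passed: in the knockdown comparison -0.438 for MYB targets, -0.304 for transcription factors, 0.461 for fibroblast markers, -0.277 for MYC program, 0.408 for interferon response and -0.257 for MYB cofactors, in the wild-type rescue comparison 0.683 for heat shock, in the rescue line comparison -0.332 for MYB targets. There, heat shock genes turned and passed as lower in the knockdown comparison at -0.261. With median-ratio scaling globins no longer passed in the knockdown (0.995). Without MYB_KnockDown replicate 1 globins no longer passed in the knockdown (0.421) or the wild-type rescue (-1.252). There, these sets newly passed: in the knockdown comparison 0.225 for apoptosis regulators and -0.209 for MYC program, in the wild-type rescue comparison -0.22 for S phase, 0.431 for heat shock and -0.35 for cholesterol synthesis, in the rescue line comparison 0.846 for globins and -0.166 for MYC program. With the length trend removed globins no longer passed in the knockdown (0.669), nor histones in the wild-type rescue (-0.422). Nor did monocyte markers in the D152V rescue (-0.955). There, these sets newly passed: in the knockdown comparison -0.255 for transcription factors, in the wild-type rescue comparison -0.281 for S phase, 0.323 for heat shock and -0.354 for cholesterol synthesis.

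With the replicate number as a block the 6 counts were 1712, 5340, 3672, 1871, 1498 and 1499, and these sets newly passed: in the wild-type rescue comparison -0.33 for cholesterol synthesis and -0.298 for hypoxia and glycolysis, in the rescue line comparison 0.846 for globins (0.75 and 2280 genes with the length trend also removed). Beyond the calls of MYB, GATA1, HBZ, SPI1 and the globins, the block changed no other call of a named gene or list between the rescue lines. In the other 5 comparisons the numbers were not shown to pair the libraries; there, UCA1 passed with the block in the wild-type rescue against control (adjusted p = 0.0186; 0.0186 to 0.205 over settings), GATA2 and SPI1 passed and S100A13 was lost in the knockdown (0.0272, 0.0181 and 0.0519), and TAL1 passed in the wild-type rescue (0.0367). Over all groups, deviations from the group means correlated from -0.042 to 0.349 over 18 pairs with the same number, 9 of them over 0.1, and from -0.256 to 0.218 over other pairs. As a hint from the data, 10 of 12 libraries correlated best with a library of their own number.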

Other observations

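The 3 tests of the ribosomal protein genes and both tests of the mitochondrial genes were chosen after their results had been seen.

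Single replication and metabolic genes passed in the rescue lines, in lists that did not pass as sets. In the wild-type rescue against the knockdown the S phase list had 2 higher and 9 lower of 28 (2 and 10 adjusted over the list alone, camera adjusted p = 0.0954). TK1, thymidine kinase, fell by 1.63 on the log2 scale (limma adjusted p = 7.15e-05), and it also fell in the D152V rescue (-0.79, adjusted p = 0.00669). Cholesterol synthesis genes had 1 higher and 6 lower of 23 (1 and 5 adjusted over the list alone, camera adjusted p = 0.0954), with EBP and NSDHL lower (-1.82 and -0.95). Hypoxia and glycolysis genes had 1 higher and 7 lower of 23 (1 and 7 adjusted over the list alone, 3 and 9 in 11 libraries, camera adjusted p = 0.0622), with the enolase gene ENO2 at -1.09. ITGA4, the integrin alpha 4 gene, rose by 2.15 (adjusted p = 1.01e-04). The S phase and cholesterol sets passed in this comparison without MYB_KnockDown replicate 1 (camera adjusted p = 0.0434 and 0.0387), as did heat shock genes (0.00531; 0.0314 to 0.692, 0.0334 to 0.717 and 1.99e-04 to 0.717 over settings). None of the 3 passed there with an estimated correlation (adjusted p = 0.760, 0.760 and 0.628).

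Single immune and signalling genes also passed, while the lymphoid, interferon and immediate early lists did not pass as sets. In the D152V rescue against the knockdown CD3G, a T cell receptor subunit, rose from 0.261 ± 0.173 to 7.20 ± 3.31 FPKM (limma adjusted p = 8.53e-05), and the lymphoid list had 2 higher and 1 lower of 4 (2 and 1 adjusted over the list alone, camera adjusted p = 0.529). ISG15, an interferon-induced modifier, fell by 1.63 while IFIH1, an RNA sensor, rose by 1.13, in a list with 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone, 4 and 1 in 11 libraries, camera adjusted p = 0.625). NR4A1, an immediate early nuclear receptor, rose by 1.28 (adjusted p = 0.00298), in a list with 4 higher and 1 lower of 17 (5 and 1 adjusted over the list alone, 3 and 2 in 11 libraries, camera adjusted p = 0.672). FOSL1, an AP-1 subunit, rose in the wild-type rescue against the knockdown by 1.70 and was lower with D152V than with wild-type MYB (-1.09, adjusted p = 0.00324). THBS1 and CD9 were higher with D152V than with wild-type MYB by 1.96 and 1.65 (adjusted p = 0.00303 and 6.56e-04).

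Ribosomal protein genes lay above other genes by 0.83 in the knockdown and by 0.32 after quantile normalization, and 3 technical sources were tested: 1 deviant library, a length bias and the siRNA itself. Without MYB_KnockDown replicate 1 the difference was 0.401 (SE 0.057 over the 2 left libraries), which argues against that library as the whole cause, though it carried more than the others at 1.69. Without it the list exceeded genes matched on transcript length (median 945 bases in both) by a median of 0.332. Of random matched lists, 95% lay at -0.113 to 0.121. That range is too narrow, taking genes as independent (the list's estimated correlation was 0.248). The match on level was incomplete (median log2 9.94 against 9.09), so differences with level stay open. Knockdown changes fell with length over all genes (rho -0.422, and -0.246 without that library, genes not being independent replicates). The 6 rescue libraries, given the same siRNA, lay at -0.348 to -0.229 against the control mean. No rescue line was given the control siRNA, so a lower starting level in those lines could hide a response to the siRNA alike in all lines. That response and a length bias stay open, as do a response to MYB depletion and library differences such as RNA quality. Each may contribute.

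MT-ATP8, MT-CO3 and MT-ATP6 are listed at 0 in the 9 libraries outside the knockdown. Mitochondrial genes are transcribed together as long precursors, and the other 10 protein genes had a median ratio of 1.575 between those 9 libraries and the 3 knockdown libraries (0.945 to 2.72 per gene), a value that could have come out far below 1. The lowest ratio, 0.945, argues against MYB level, the biological explanation the design gives, acting on mitochondrial transcription as the cause of the 0 values. The ratios are consistent with estimates that failed in the authors' quantification. No other biological explanation was tested.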
